A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

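Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mononucleosomes from cells of 2 lines, mouse MMTV-Myc cells and human MDA-MB-231-Luc cells. MDA-MB-231 is an established human breast cancer line, and the name MMTV-Myc is used for mouse mammary tumours driven by a Myc transgene. Per the labels' protocols, cells were infected with lentivirus carrying a short hairpin RNA against Cbx8 or a scrambled control, selected with puromycin, and their chromatin was digested with micrococcal nuclease. Libraries were read as single-end reads of 100 bp. The series holds 10 libraries in 10 groups, 7 from MMTV-Myc and 3 from MDA-MB-231-Luc, with 1 library per combination of line, hairpin and antibody. Samples were grouped by the line, hairpin and antibody that their labels name.

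The deposited files are 8 lists of regions with 3 columns (chromosome, start and end). The authors' lists hold regions that were lower, or higher, in a knockdown library than in its scrambled control. They carry no score, fold, p-value or read count, so the depth of the libraries and the size of each change are unknown here. Per the names of the deposited lists, the MMTV-Myc lists were called at a fold of 1.8 and a q-value of 1e-08, and the MDA-MB-231-Luc lists at a q-value of 0.002 with no fold named. Per the submitters' processing notes, FastQC 0.10.0, Bowtie 1.0.0, MACS2 2.1.0 and SICER were used, with the builds mm9 for mouse and hg19 for human. Which of these tools called the changed regions is not given in the sources used here, nor is the use of the input libraries or any scaling for depth. Because only regions past the authors' thresholds are listed, a site missing from the lists is not shown to be unchanged.

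In the 8 lists, 0 starts lay off a grid of 50 bp, and each end lay 1 bp below a grid position. Regions were therefore read as starting at a count from 0 with the end position included, and lengths were computed on that reading. Coordinates are printed counted from 1. No list held a duplicate or overlapping region. The gene table at hand was for the mouse assembly GRCm38.p6, and 14 mouse regions, on 1 chromosome, began beyond the last gene of that table, so its positions were not used. With no annotation of mm9 or hg19 used here, regions are reported by position and were not tied to genes. The planned comparisons of promoter overlap, of gene lists and of genes shared by the 2 lines were not run.

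For each of the 4 comparisons, lower and higher regions were counted, and the lower share was given a 95% Clopper-Pearson interval. These intervals cover counting error over regions only. Each condition had 1 library, so no test between conditions was possible and no difference has a replicate check. Overlap between marks required at least 1 bp and was counted with bedtools 2.31.1. It was set beside 1000 random placements of the regions on their own chromosomes, within the span from position 0 to the last region end in any list of that organism. Random placement ignores where promoters lie, so it describes the lists and is not a test of the marks. Lengths of lower and higher regions were compared by a two-sided permutation test of medians, with 100000 permutations, or by exact enumeration for the list of 2 regions. Such tests take regions, not cultures, as units. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

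The code was tested on simulated data. All 50 overlaps planted among the 166 lower H3K27ac positions of MMTV-Myc were found. Randomly assigned directions at the 3852 MDA-MB-231-Luc positions exceeded the upper bound of the permuted range in 3 of 40 draws, where 1 was expected. The length test called 2 of 40 draws with equal lengths and 40 of 40 draws with lengths 1.5 times larger, at 100 regions per draw.

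The regions named in the text are the 5 longest of each list, or all where a list has 5 or fewer, and up to 10 shared by marks. This rule and the list of alternatives below were fixed before the data were examined. Regions named outside it are said to be chosen after their values were seen. The alternatives were a minimum length at the median of each comparison, merging of regions closer than 5000 bp, base pairs covered in place of counts, autosomes only, other definitions of overlap, and merging within 100000 bp for the shares per chromosome.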

Results

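The data covered 3 histone modifications in MMTV-Myc cells and 1 in MDA-MB-231-Luc cells, each compared between cells with a hairpin against Cbx8 and cells with a scrambled hairpin. Cbx8 is a chromodomain protein of Polycomb repressive complexes. The study's title pairs it with Wdr5, a subunit of histone H3 lysine 4 methyltransferase complexes, in mammary tumour formation. H3K4me3 marks active promoters, H3K27ac marks active promoters and enhancers, and H3K27me3 is the mark laid down by Polycomb complexes. The values available were the positions of regions that the authors called lower or higher after knockdown, with 1 library per condition. No difference reported here therefore has a replicate check, and read depth is unknown.

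In MMTV-Myc cells, H3K4me3 was called lower at 701 regions and higher at 18 regions after Cbx8 knockdown, which is 38.9 lower regions for each higher one. Lower regions made up 97.5% of the 719 changed regions (95% interval 96.1 to 98.5%, regions as units). The lower regions covered 1.42 Mb and the higher regions 40.15 kb. The longest lower region spanned 7.85 kb on chromosome 5 (mm9, 116009101 to 116016950). It was followed by 6.6 kb on chromosome 11 (117683551 to 117690150), 5.8 kb on chromosome 11 (98565551 to 98571350), 5.45 kb on chromosome 10 (79781801 to 79787250) and 5.4 kb on chromosome 5 (23895801 to 23901200). The longest higher region spanned 3.75 kb on chromosome 19 (34714351 to 34718100). The next were 3.4 kb on chromosome 5 (115346701 to 115350100), 3.1 kb on chromosome 15 (74825751 to 74828850), 3.05 kb on chromosome 3 (151410051 to 151413100) and 2.75 kb on chromosome 19 (34681601 to 34684350).

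Lower H3K4me3 regions were found on all 20 chromosomes present in the mouse lists. Chromosome 4 held 74 of the 701, or 10.6% of the list (95% interval 8.38 to 13.1%), against 6.29% of the span covered by the lists. Chromosome 11 held 63 regions, 8.99% of the list against 4.90% of the span. Chromosome X held 20 regions, 2.85% of the list against 6.13% of the span, and chromosome 3 held 18, 2.57% against 6.12%. These chromosomes were picked from the 20 for their shares. The span does not follow the density of promoters or genes, so these contrasts do not show enrichment. Among windows of 1 Mb, chromosome 10 from 79 to 80 Mb held 9 lower regions and 0 higher regions, the most of any mouse window. Chromosome 7 from 148 to 149 Mb followed with 7 lower and 0 higher regions. These windows were chosen after their values were seen. Lower and higher regions had similar lengths, with medians of 1850 bp (n = 701) and 1900 bp (n = 18), and the difference of 50 bp did not pass a two-sided permutation test (p = 0.83).

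**Figure D1:**
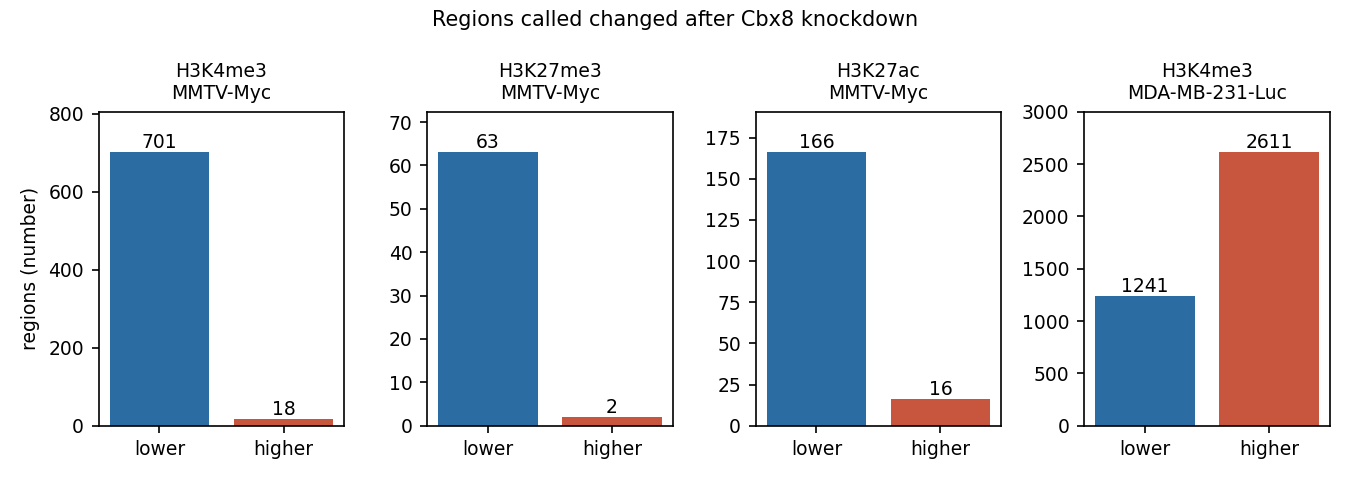
Number of regions the authors called lower or higher after Cbx8 knockdown, for each mark and cell line. Each panel has its own vertical axis from 0, and the number stands above each bar. The MMTV-Myc panels are dominated by lower regions (701, 63 and 166), while the MDA-MB-231-Luc panel has 1241 lower and 2611 higher regions.

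H3K27ac in MMTV-Myc cells was called lower at 166 regions and higher at 16 regions. Lower regions were 91.2% of the 182 changed regions (95% interval 86.1 to 94.9%). The longest lower region spanned 6.6 kb on chromosome 5 (143655101 to 143661700). Those next in length were on chromosome 13 (30073451 to 30079850, 6.4 kb), chromosome 2 (154393301 to 154399600, 6.3 kb), chromosome 8 (86589051 to 86594550, 5.5 kb) and chromosome 11 (115881001 to 115886400, 5.4 kb). The longest higher regions were on chromosome 7 (113378251 to 113383400, 5.15 kb), chromosome 19 (34680851 to 34684100, 3.25 kb) and chromosome 17 (26862651 to 26865850, 3.2 kb). Regions of 2.4 kb on chromosome 14 (30160951 to 30163350) and chromosome 7 (50983401 to 50985800) came next. Chromosome 2, picked as the chromosome with the most, held 22 of the 166 lower regions. This was 13.3% of the list (95% interval 8.50 to 19.4%) against 7.28% of the span, which does not follow gene density. The median length was 2000 bp for lower regions and 1475 bp for higher regions, a difference that did not pass a two-sided permutation test (p = 0.13).

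H3K27me3 in MMTV-Myc cells was called changed at 65 regions, 63 lower and 2 higher, so lower regions were 96.9% (95% interval 89.3 to 99.6%). The longest lower region spanned 7.5 kb on chromosome 12 (110792651 to 110800150). It was followed by regions on chromosome 11 (19087551 to 19093400, 5.85 kb), chromosome 17 (65584151 to 65589950, 5.8 kb), chromosome 19 (27517201 to 27522950, 5.75 kb) and chromosome 3 (24750051 to 24755750, 5.7 kb). Both higher regions were shorter, with 2.75 kb on chromosome 4 (18008151 to 18010900) and 2.25 kb on chromosome 2 (166589101 to 166591350). Chromosome 13, picked as the chromosome with the most, held 9 of the 63 lower regions. This was 14.3% of the list (95% interval 6.75 to 25.4%) against 4.47% of the span, which does not follow gene density. The median length of 3800 bp for lower regions and 2500 bp for higher regions gave a difference that did not pass an exact two-sided permutation test (p = 0.13).

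The next comparison was whether the marks changed at the same places in MMTV-Myc cells. Of the 166 lower H3K27ac regions, 4 overlapped a lower H3K4me3 region, or 2.41% (95% interval 0.66 to 6.05%). Random placement gave 0.245 on average and at most 3, but it ignores where promoters lie, so the excess is not a test of joint change. On chromosome 1, the H3K27ac region at 93354351 to 93356900 contained the whole H3K4me3 region at 93354801 to 93356700. On chromosome 2, the H3K27ac region at 154393301 to 154399600 contained the H3K4me3 region at 154393601 to 154397150. On chromosome 17, the H3K27ac region at 29230801 to 29234500 shared 3150 bp with the H3K4me3 region at 29230251 to 29233950. On chromosome 1, the region at 79854951 to 79858500 shared 1050 bp with that at 79853551 to 79856000. With a distance of up to 5000 bp in place of an overlap, 7 regions were shared.

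Among regions called higher, 1 of the 16 H3K27ac regions overlapped 1 of the 18 H3K4me3 regions, on chromosome 19 (34680851 to 34684100 for H3K27ac, 34681601 to 34684350 for H3K4me3), sharing 2500 bp. Overlaps between a lower region of H3K4me3 and a higher region of H3K27ac, or the reverse, numbered 0. Of the 63 lower H3K27me3 regions, 0 overlapped a changed region of H3K4me3 or of H3K27ac in either direction, which allows a share of up to 5.69% (upper bound of the exact 95% interval). Random placement against the lower H3K4me3 regions gave 0.129 on average, so a count of 0 could not have fallen below random placement. Neither of the 2 higher H3K27me3 regions overlapped a changed region of another mark.

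**Figure D2:**
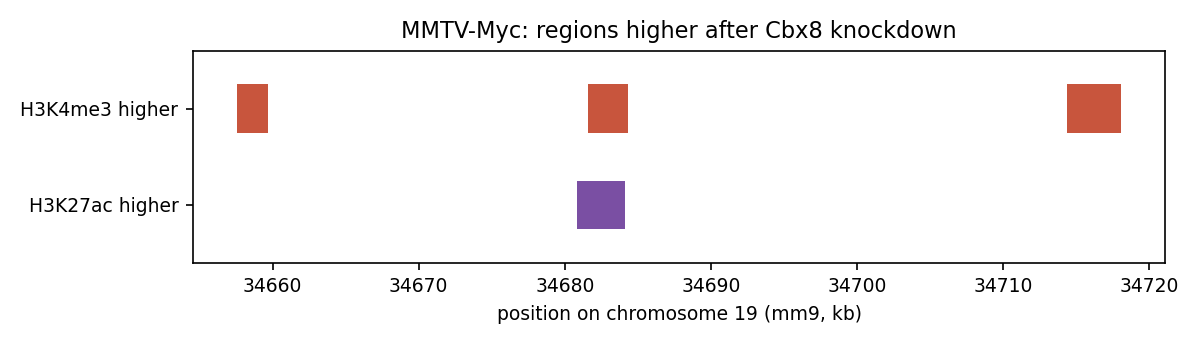
Map of the regions called higher after Cbx8 knockdown in MMTV-Myc cells on part of chromosome 19 (mm9, position in kb, to scale). The upper row shows the 3 H3K4me3 regions, which lie within 60.55 kb, and the lower row the H3K27ac region, which shares 2500 bp with the middle one.

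In MDA-MB-231-Luc cells, H3K4me3 was called lower at 1241 regions and higher at 2611 regions after CBX8 knockdown. Lower regions were 32.2% of the 3852 changed regions (95% interval 30.7 to 33.7%), and there were 2.1 higher regions for each lower one. The base pairs covered did not follow the counts, with 6.17 Mb in lower regions and 5.89 Mb in higher regions, or 51.2% lower. The longest lower region spanned 21.65 kb on chromosome 1 (hg19, 94693751 to 94715400). The next was 16.5 kb on the mitochondrial chromosome (51 to 16550), whose DNA is not packaged in nucleosomes, so this call does not show a change of H3K4me3. Lower regions of 16.35 kb on chromosome 1 (156082651 to 156099000), 15.95 kb on chromosome 11 (122037151 to 122053100) and 14.85 kb on chromosome 10 (22603051 to 22617900) followed. The longest higher regions were on chromosome 8 (145008201 to 145028300, 20.1 kb), chromosome 15 (96867401 to 96883800, 16.4 kb) and chromosome 10 (4802051 to 4815050, 13.0 kb). The next were on chromosome 8 (77314151 to 77327050, 12.9 kb) and chromosome 22 (46460351 to 46473150, 12.8 kb).

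Direction went with region length in MDA-MB-231-Luc cells. The median lower region was 4400 bp long (interquartile range 3350 to 5950 bp, n = 1241) and the median higher region 1750 bp (1150 to 2800 bp, n = 2611). The ratio of medians was 2.51, and the difference of 2650 bp gave p = 2e-05 in a two-sided permutation test, the smallest that 100000 permutations can give. In the shortest decile of changed regions, 0 of 386 were lower, which allows a share of up to 0.951% (exact 95% interval). In the longest decile, 6000 to 21650 bp long, 304 of 386 were lower, or 78.8% (95% interval 74.3 to 82.7%). Among regions at least as long as the median of all changed regions, 1148 were lower and 803 higher when all of them were pooled. By decile, lower regions were 35.1% of those from 2500 to 3150 bp and 48.6% of those from 3150 to 3800 bp. They were the majority from 3800 to 4650 bp (67.0%) and above.

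**Figure D3:**
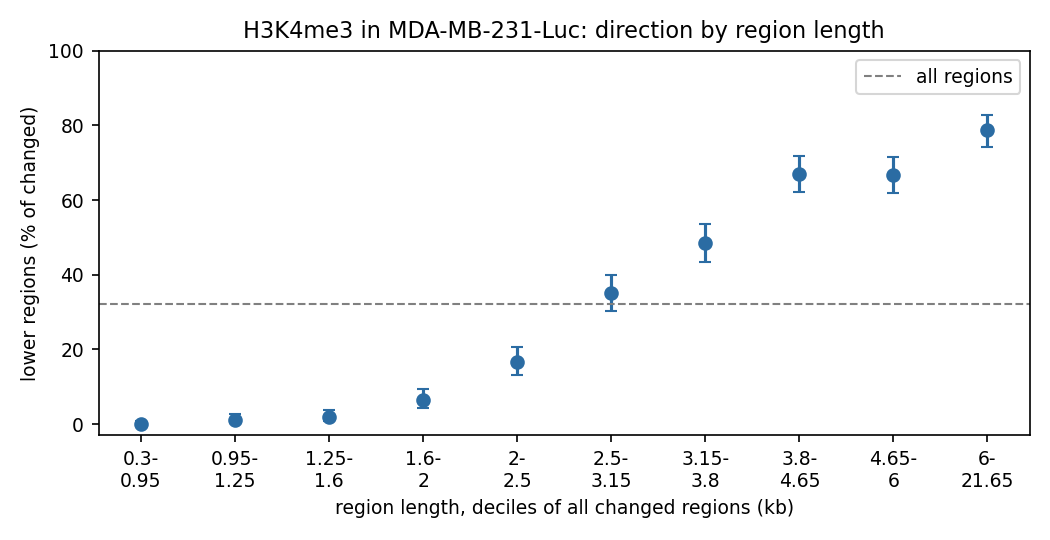
Share of changed H3K4me3 regions called lower in MDA-MB-231-Luc cells (vertical axis, percent) in deciles of region length (horizontal axis, range of each decile in kb). Points are shares, bars are exact 95% intervals over regions, and the dashed line is the share over all regions (32.2%). The share goes from 0 in the shortest decile to 78.8% in the longest.

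The balance also differed between human chromosomes. Lower regions were 57.0% of the 149 changed regions of chromosome 19 (95% interval 48.7 to 65.1%) and 53.6% of the 166 of chromosome 14 (45.7 to 61.4%). On chromosome 6 they were 42.0% of 312 (36.5 to 47.7%). They were 20.2% of the 119 on chromosome 9 (13.4 to 28.5%) and 20.0% of the 75 on chromosome 18 (11.6 to 30.8%). The shares that region length alone would give were 37.5% for chromosome 19, 44.7% for chromosome 14, 35.4% for chromosome 6, 28.9% for chromosome 9 and 25.9% for chromosome 18. The length share lay inside the interval for chromosome 18 and close to a bound for chromosomes 14, 6 and 9. These chromosomes were picked for their high or low shares. Adjacent regions tended to share a direction, as given below. The intervals take regions as independent, so they are too narrow to judge departures from the length shares. On chromosome 6 from 26 to 29 Mb, chosen after its values were seen, 42 of 50 changed regions were lower, or 84.0% (70.9 to 92.8%). In the rest of chromosome 6 lower regions were 34.0% of 262 (28.3 to 40.1%). Region length alone, by the trend over all chromosomes, would give 50.7% in that window and 32.5% in the rest of the chromosome. Inside the window direction did not follow that trend, with medians of 3475 bp for the 42 lower and 4700 bp for the 8 higher regions. Whether length accounts for part of the contrast is thus not settled. The windows of 27 to 28 Mb and 28 to 29 Mb held 23 and 19 changed regions, the most of any 1 Mb window in the human lists. On chromosome 10 from 3 to 4 Mb, also chosen after its values were seen, 10 of 11 changed regions were higher.

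**Figure D4:**
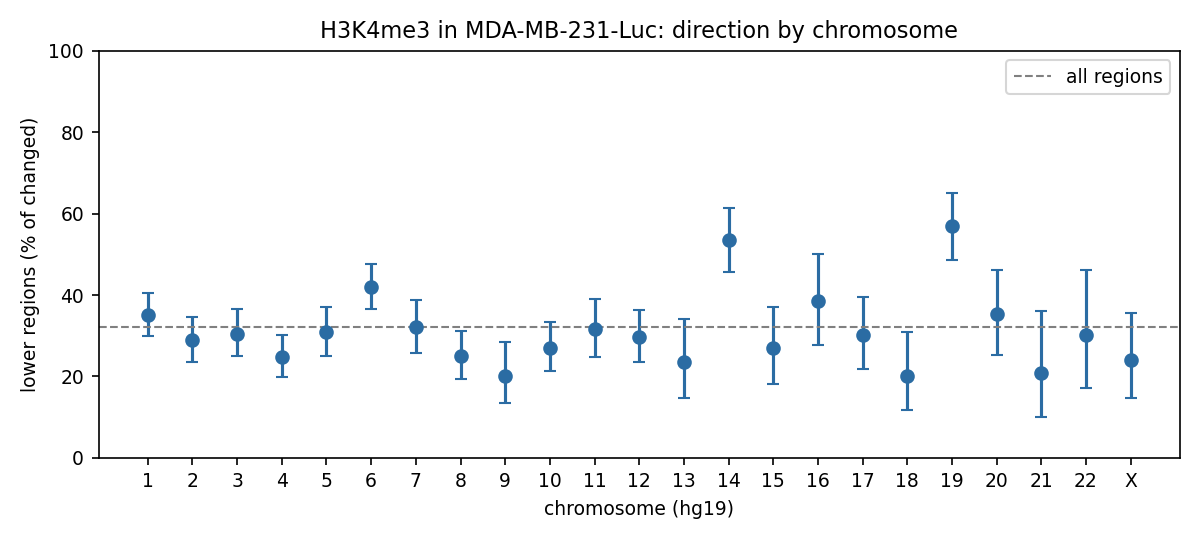
Share of changed H3K4me3 regions called lower in MDA-MB-231-Luc cells (vertical axis, percent) on each chromosome (horizontal axis, hg19). Points are shares, bars are exact 95% intervals over regions, and the dashed line is the share over all regions (32.2%). Chromosomes 14 (53.6%) and 19 (57.0%) lie highest, and the single mitochondrial region is not drawn.

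H3K4me3 after knockdown was thus compared in both lines. The lower share was 97.5% of 719 regions in MMTV-Myc and 32.2% of 3852 in MDA-MB-231-Luc, a gap of 65.3 percentage points. The lists of the 2 lines were called at different thresholds, in different species and with 1 library per condition, so this gap was not tested between conditions.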

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

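Among the tests in this part, the shares by position quintile of a chromosome, the length-expected share of chromosomes 14 and 19 together and the merging of close regions were set before their results were seen. The other tests were chosen after the results were seen.

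The lower share of changed H3K4me3 regions stood apart between the cell lines, by 65.3 percentage points (97.5% in MMTV-Myc, 32.2% in MDA-MB-231-Luc), and this difference was not tested between conditions. A minimum length in the human lower list, whose shortest region is 1000 bp while 406 higher regions are shorter, was weighed as an explanation. Among human regions of at least 1000 bp the lower share was 36.0% (95% interval 34.4 to 37.6%). A hard limit at 1000 bp would thus not by itself account for a share below 50%. That cut could only take out higher regions, and 2205 of them remained beside 1241 lower ones. A higher or gradual length limit was not tested, and the share was 58.8% among regions at least as long as the median. The threshold stays open, since the mouse lists name a fold of 1.8 and a q-value of 1e-08 and the human lists only a q-value of 0.002, and no list holds a fold or q per region. With length in place of strength, human regions of at least 6000 bp were 78.3% lower (306 of 391), but length is not the threshold, so threshold, line, species and library cannot be told apart here.

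The gap in median length between lower and higher H3K4me3 regions also stood apart between the lines, at 2650 bp in MDA-MB-231-Luc and -50 bp in MMTV-Myc. The difference of 2700 bp had a bootstrap interval of 2500 to 3400 bp over 10000 draws of regions, which takes regions as units and rests on 18 higher regions in the mouse.

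Changed regions on human chromosomes 14 and 19 were lower more often than the 32.2% of all regions. The share there was 55.2% of 315 (95% interval 49.6 to 60.8%, which includes 50%). Their region lengths alone would give 41.3% lower (44.7% for chromosome 14, 37.5% for chromosome 19). Resampling blocks of 1 Mb, the observed share exceeded its length share by 8.92 points on chromosome 14 (95% interval 3.07 to 14.8). On chromosome 19 the excess was 19.6 points (11.0 to 28.0). Intervals with larger blocks were not computed. In the shuffles described below, the upper bound for chromosome 14 itself rose from 42.6% with 1 Mb blocks to 48.1% with 10 Mb blocks. Its interval above is thus probably too narrow, and length as the whole cause stays open for chromosome 14. The larger excess on chromosome 19 argues against length as the whole cause there, though these chromosomes were picked as the highest. Regions near one another also tended to share a direction: 65.1% of 3828 adjacent pairs agreed, against 60.2% as the highest of 10000 permutations within chromosomes. Merging regions of a list closer than 100000 bp left the lower share at 53.9% of 128 on chromosome 14 (95% interval 44.9 to 62.8%) and 55.0% of 111 on chromosome 19 (45.2 to 64.4%), against 32.8% of all merged regions. With blocks of 1, 5 or 10 Mb kept whole and shuffled over all chromosomes, the 2 highest of 21 chromosomes (those with at least 50 changed regions) reached 55.2% in 0, 6 and 20 of 10000 shuffles. The highest chromosome of a shuffle reached the 57.0% of chromosome 19 in 3, 138 and 308 of 10000 shuffles. The next highest reached the 53.6% of chromosome 14 in 0, 1 and 3. These counts argue against runs of like neighbours up to those sizes as the whole cause when taken alone, less strongly for chromosome 19 at the larger blocks. The shuffles compared shares not adjusted for region length, so they do not speak to runs and length acting together. A difference in copy number of the whole chromosome between the libraries remains a candidate explanation, which the position quintiles cannot decide. In each quintile of both chromosomes the lower share exceeded the 32.2% of all regions. The smallest was 39.4% of 33 regions (95% interval 22.9 to 57.9%) at the far end of chromosome 14. That value lay below the 44.7% that length alone would give for chromosome 14, and its interval holds both baselines. No biological explanation was tested, since the design names none for these chromosomes.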

How the results depend on the processing

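Of 54 alternative values over 26 results, 46 kept their direction and stayed within the interval, the 1.5-fold range or the side of the threshold used to judge them. Many of these 46 are overlap counts between marks that were 0 and stayed 0. A stricter definition of overlap could not have changed a count of 0, so the number 46 overstates how much was put to the test. The human balance of H3K4me3 regions was the result that turned. Its lower share of 32.2% became 58.8% among regions at least as long as the median and 51.2% of base pairs covered. In alternatives chosen after seeing the data it was 78.3% among the 391 regions of at least 6000 bp, 36.0% among regions of at least 1000 bp and 30.2% without chromosomes 14 and 19. By construction, these settings keep or weight long regions, except the last, which leaves out 2 chromosomes. The lower share of H3K27me3 in MMTV-Myc became 100% (33 lower, 0 higher) at the median length, since both higher regions are shorter than it. Shared lower regions of H3K27ac and H3K4me3 numbered 7 within 5000 bp in place of 4. The largest share of the human lower list on 1 chromosome was 8.18% after merging within 100000 bp, in place of 10.6% on chromosome 6 before it. The mouse H3K4me3 lower share lay between 97.2% and 98.0% under its alternatives, including 1 chosen after seeing the data. Alternatives based on promoters, gene lists and genes shared by the lines were not run, as no annotation of the builds was used here. With region lists alone, depth and the size of each change are unknown, and no list has a replicate.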

Other observations

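Higher H3K4me3 regions of MMTV-Myc lay close together: 7 of the 18 fell into 3 groups with gaps under 200 kb. Chromosome 19 held 3 of these higher regions within 60.55 kb (34657551 to 34659700, 34681601 to 34684350 and 34714351 to 34718100). Chromosome 7 held 2 within 21.15 kb (111593151 to 111594900 and 111612501 to 111614300), and chromosome 18 held 2 within 172.2 kb (60371301 to 60373100 and 60541701 to 60543500). The middle chromosome 19 region also carried a higher H3K27ac region. Of the 701 lower H3K4me3 regions, 254 (36.2%) also had another lower region within 200 kb, in a list far longer.

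The distance of 200 kb, and the test of chance, were chosen after these positions were seen, so the closeness is a hypothesis found and tested on the same regions. To lessen the weight of that distance, close pairs were counted at 5 distances (50, 100, 200, 500 and 1000 kb), giving 3, 4, 5, 5 and 5 pairs. Of 10000 random draws of 18 from the 719 changed H3K4me3 regions, 1, 0, 0, 2 and 5 had as many pairs at these distances. Taking for each draw its rarest count over the 5 distances, 0 draws had a count as rare as the rarest of the higher regions. With 0 draws at 100 and 200 kb already, this adds little to the counts per distance. In another set of 10000 draws, 1 had as many pairs within 200 kb. The counts per distance argue against chance placement among the changed H3K4me3 regions, as far as a test on the regions that prompted it can. The search for lower regions inside the chromosome 19 interval was set before its result was seen. A copy number gain across the chromosome 19 interval in the knockdown library remains a possible explanation, as the number of lower regions of any mark inside it was 0, which neither the presence of a gain nor its absence forbids. Whether the groups are families of related genes was not tested, as no annotation of the build was used here.

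Lower H3K27ac regions of MMTV-Myc lay near lower H3K4me3 regions more than random placement gave. Within 100 kb of a lower H3K4me3 region lay 36 of 166, or 21.7% (95% interval 15.7 to 28.7%), against 5.67% on average under random placement. Of these 36, 4 overlapped and 32 did not. For lower H3K27me3 regions the number was 3 of 63, or 4.76% (95% interval 0.99 to 13.3%), against 5.0% under random placement. Random placement does not follow the density of genes, and the distance of 100 kb was chosen after the lists were seen.

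The human lower list contains 1 region on the mitochondrial chromosome, 16.5 kb long and at position 6 of 1241 in the order of the file. Mitochondrial DNA is not packaged in nucleosomes, so this call does not show a change of H3K4me3. What gave rise to it was not tested, nor whether it bears on other regions of the list.

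The deposited lists are not sorted by position, and their order relates to length in different ways. Across regions, which are not independent replicates, Spearman's rho between place in the list and length in MMTV-Myc was -0.75 for the 701 lower and 0.064 for the 18 higher H3K4me3 regions. It was 0.82 for the 166 lower and 0.89 for the 16 higher H3K27ac regions, and 0.80 for the 63 lower H3K27me3 regions. In the human lists it was -0.34 for the 1241 lower and -0.17 for the 2611 higher regions. It was not computed for the list of 2 higher H3K27me3 regions. The quantity the lists were ordered by is not given in the sources used here.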
